A study of Mus musculus with 18 samples.

How the data were processed

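Total RNA of 18 samples had been labelled as biotinylated cRNA and hybridized by the authors to mouse Illumina whole-genome BeadChips with 45281 probes. Per the file headers, the non-normalized table gives for each array the mean bead signal of each probe, an intensity that is neither background-corrected nor normalized between arrays. Its second kind of column is, per the file headers, the detection p-value (p_value) of each probe on that array. The deposited series value table holds intensity on a linear scale. Its columns share nearly the same distribution and keep the ranks of the non-normalized signal, as quantile normalization by the authors would give; the method is not given in the sources used here. GenomeStudio made the tables, in a version not given in the sources used here. The file headers also name the BeadChip of each array, 4 chips in all.

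All 18 arrays were used, in 6 groups of 3 taken from the labels. The non-normalized signal was background-corrected and quantile-normalized with neqc of limma 3.58.1 in R 4.3.3, with the negative control distribution inferred from the detection p-values and an offset of 16. Probes with a detection p under 0.01 on at least 3 arrays were kept, 15987 of them. Symbols came from the probe table of the platform, updated through Entrez identifiers to current names of assembly GRCm38.p6: 34885 probes had 1 symbol, 10378 had none and 18 had several, and these last were treated as unnamed. Each symbol was represented by its probe with the highest mean log2 intensity, which left 11109 entries, 8919 named genes and 2190 unnamed probes. Probe positions are not printed, as the build used for the probes is not given in the sources used here. Among the 3381 genes with several kept probes, 105 had probes called in opposite directions for the RIG-I ligand in wild-type cells and 18 in the genotype by RIG-I ligand interaction.

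A linear model with 6 group means was fitted with lmFit, and 11 contrasts were tested with moderated statistics (eBayes, 12 residual and 4.777 prior degrees of freedom, 2-sided). P-values were adjusted by Benjamini-Hochberg within each contrast, and the threshold was 0.05. The standard error is that of the moderated fit. Where no array of a group detected a gene, its level was set to the lowest detected level of each array in place of its own value, where that was higher, and the fold is given as a lower bound. Medians of lists with such genes are also given at that floor in the closing section. The labels do not say whether untreated cells received the transfection reagent, Lipofectamine 2000.

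The 26 gene lists were fixed before the data were examined, as were the comparisons, the test, the rule for named genes and the alternatives. Lists were interferon genes, interferon-stimulated genes, chemokines, inflammatory cytokines and NF-kB targets, immediate early genes, the nucleic acid sensing pathway, the OAS and RNase L system, antigen presentation by MHC class I, ribosomal proteins, oxidative phosphorylation, replication-dependent histones, cell cycle, the integrated stress response, heat shock, p53 targets, NRF2 targets, cholesterol synthesis, markers of macrophages, neutrophils, lymphocytes, dendritic cells, fibroblasts, erythroid and mast cells, sex-linked genes, and chromosome 1 neighbours of Rnasel. For each list and contrast, members past the threshold were counted after adjustment over all entries and over the list alone. Lists with at least 3 members were tested with camera, with a preset correlation of 0.01 and again with an estimated one, each adjusted over all lists and contrasts. Named genes were the 8 largest rises and falls per contrast among genes past the threshold, detected on all arrays of a group and without overlap between groups, up to 3 members of each list with the smallest p, and a fixed panel.

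The fit and the list test were tested on simulated data with the spreads of these arrays and the means of the untreated wild-type arrays, in which the knockout RIG-I ligand arrays alone were changed. Of 50 genes changed by 0.5 log2 units 33 were called in the treatment contrast and 15 in the interaction. For a change of 1 the numbers were 46 and 39, and for a change of 2 all 50 were called in each, with 6 and 3 false calls among the unchanged genes. A list moved by simulation was found in all 4 contrasts that hold those arrays, and no other list test passed. Genes were simulated independently of each other and only the preset correlation was run. The simulation thus does not show how that test behaves with lists of correlated genes.

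The arrays detected between 11824 and 15048 probes each, and correlations between replicates ranged from 0.9927 to 0.9976. Alternatives covered background correction, normalization, the filter, the choice of probe, the deposited values, the empirical Bayes step, array weights, the groups in the fit, a fold threshold, the replicate number as a block, and leaving out each array. A BeadChip block was not run, as group membership fixes the chip of every array and the block would add no term that could be estimated.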

Results

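Gene expression was measured in bone marrow-derived macrophages of C57BL/6 mice, either wild-type or lacking Rnasel. Rnasel encodes RNase L, an endoribonuclease switched on by oligoadenylates. The 18 arrays fell into 6 groups of 3. Cells of each genotype were left untreated, given 1 µg per well of a ligand of RIG-I, a cytosolic sensor of viral RNA, or given 5 µg per well of calf thymus DNA (CT DNA). Both ligands were delivered by transfection, and cells were taken after 6 h. Of 45281 probes, a mean of 14750.7 ± 264.9 (SD, n = 3) were detected in untreated and 13338.3 ± 249.3 in RIG-I ligand wild-type cells, and 12848.7 ± 355.9 in wild-type cells given CT DNA. The knockout groups had 14368.3 ± 594.4 detected probes untreated, 12001 ± 203.3 with the RIG-I ligand and 13124.3 ± 150.5 with CT DNA. The number of arrays limits the precision of every value. Wild-type untreated and RIG-I ligand cells shared 1 BeadChip, the knockout groups of the same treatments shared another, and the CT DNA group of each genotype had a chip of its own. Responses to the RIG-I ligand were thus measured within chips, and an additive chip difference cancels when they are compared between genotypes. Each genotype still had its own chip there, and in every other comparison chip and group cannot be told apart. Genes said to rise, fall or differ had an adjusted p under 0.05 in limma, and values are log2 fold changes with their standard error (SE) for 3 arrays per group. The replicates are described only as triplicates, so p-values measure the spread between these samples, which may be technical. The median of all 11109 genes and unnamed probes tested was -0.145, -0.177, -0.198 and -0.176 for the RIG-I ligand and CT DNA in wild-type, then in knockout cells. With each array scaled to a common median it was -0.758, -0.795, -0.744 and -0.335, so the balance of rises and falls depends on the scaling. For instance 1180 genes rose and 8202 fell with the RIG-I ligand in wild-type cells under that scaling. The common median was taken over all 45281 probes, and most probes were undetected on each array. Median scaling thus aligns the arrays at background level rather than on expressed genes. With 75th percentile scaling the median of the tested genes was -0.153, -0.0998, -0.136 and -0.089. For each list of genes the adjusted p of the camera test is given with a preset correlation, then with one estimated from the arrays. Adjustment over the list alone gave the same counts of genes where no other count is given.

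**Figure D1:**
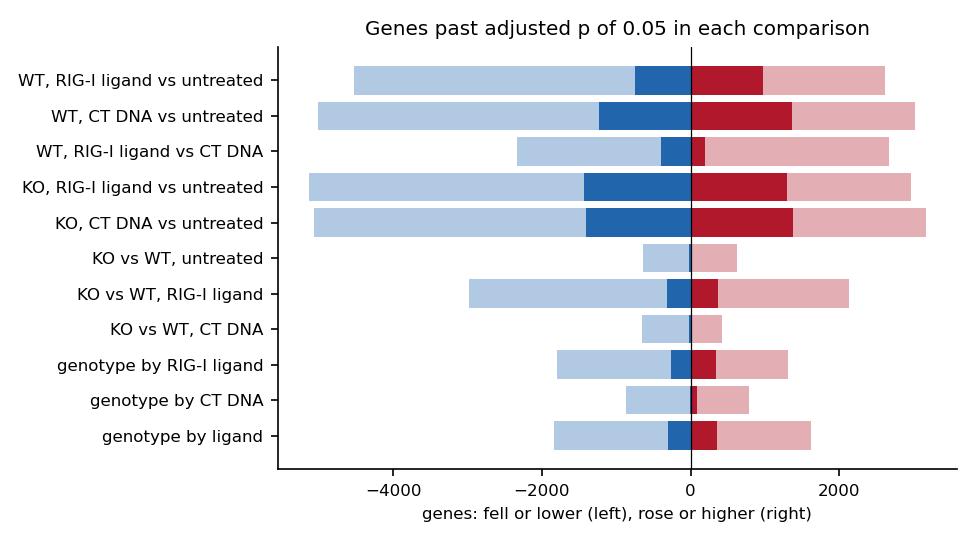
Number of genes past an adjusted p of 0.05 in each of the 11 comparisons (n = 3 arrays per group), lower or fallen to the left and higher or risen to the right; dark bars are those that also changed by at least 1 log2 unit. KO is knockout and WT is wild-type; 608 genes passed both criteria in the genotype by RIG-I ligand interaction and 100 in the genotype by CT DNA interaction.

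The response of wild-type cells to the RIG-I ligand was measured against untreated cells, which may not have received the transfection reagent. Ligand and transfection thus cannot be told apart in any comparison with untreated cells. Interferon genes and their targets rose most. Ifnb1, encoding interferon beta, was not detected in untreated cells and rose at least 277-fold. In all, 11 of 13 interferon genes rose while 2 did not pass (camera adjusted p = 1.0e-13, and 0.0064 with an estimated correlation). The interferon alpha genes among them, such as Ifna11 (at least 278-fold) and Ifna5 (at least 264-fold), are near-identical copies whose probes may cross-hybridize. Of 60 interferon-stimulated genes 58 rose, none fell and 2 did not pass (camera adjusted p = 2.9e-34, and 0.013 with an estimated correlation). Examples are Oasl1 (4.76, SE 0.0866), Mx2, an antiviral GTPase (4.44, SE 0.0937), Tnfsf10, the death ligand TRAIL (4.77, SE 0.0819), and Isg15, a ubiquitin-like modifier (3.67, SE 0.129). Among 16 chemokines 14 rose and 1 fell (camera adjusted p = 6.6e-11, and 0.025 with an estimated correlation). Cxcl10 (6.59, SE 0.105), Cxcl9 (6.35, SE 0.072) and Ccl5 (5.80, SE 0.15), which attract T cells, led this group. The probe of Cxcl10 was near the top of the measured range in every treated group of both genotypes, so its rises may be underestimated. Ifnb1 also came close to it after CT DNA in both genotypes and after the RIG-I ligand in knockout cells. Only 33 to 51 genes had a higher mean level than Ifnb1 in those groups, so its differences may be compressed too.

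Of 40 inflammatory cytokines and NF-kB targets 36 rose, none fell and 4 did not pass (camera adjusted p = 6.0e-21, and 0.0018 with an estimated correlation). The early activation marker Cd69 (7.10, SE 0.127), the costimulatory receptor Cd40 (4.10, SE 0.0734) and Tnf (3.13, SE 0.09) rose strongly. Il6 and Il1b, not detected in untreated cells, rose at least 1.38-fold and at least 1.68-fold, and Il27 at least 16.2-fold. The nucleic acid sensing pathway had 19 of 24 genes up and 3 down (camera adjusted p = 1.4e-08, and 0.0018 with an estimated correlation), with Casp4, the mouse caspase-11 (3.52, SE 0.0811), and the necroptosis effector Mlkl (2.29, SE 0.0754). Antigen presentation by MHC class I had 20 of 22 genes up and 2 not passing (camera adjusted p = 2.4e-11, and 0.017 with an estimated correlation), among them its transactivator Nlrc5 (2.86, SE 0.0754) and the peptide transporter Tap1 (2.80, SE 0.0963). Immediate early genes rose in 13 of 22 cases and fell in 5, or 11 and 10 with median scaling (camera adjusted p = 0.0014, and 0.092 with an estimated correlation). Examples are Dusp2 (3.29, SE 0.0825), Egr1 (2.29, SE 0.186) and Ier2 (at least 6.19-fold). The heat shock chaperone gene Hspa1a rose by 3.92 (SE 0.09). Of 12 heat shock genes 4 rose and 4 fell, or 3 and 7 with median scaling (camera adjusted p = 0.31, and 0.37 with an estimated correlation).

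Replication-dependent histone genes rose in 21 of 40 cases and fell in 10, or 18 and 20 with median scaling (camera adjusted p = 0.0031, and 0.18 with an estimated correlation), with H3c4 (2.60, SE 0.0898), H3c1 (2.46, SE 0.107) and H2bc21 (2.17, SE 0.0958) up. For H2bc21, kept probes were called in opposite directions here, so that value rests on 1 probe. Cell cycle genes fell in 26 of 30 cases and rose in 1 (camera adjusted p = 1.2e-05, and 0.013 with an estimated correlation), among them E2f1, a driver of S phase entry (-1.58, SE 0.0958), and the replicative helicase gene Mcm4 (-1.28, SE 0.0767). Further falls were seen in Sesn1, encoding a stress-inducible sestrin (-3.28, SE 0.131), Cdca7 (-3.28, SE 0.185), the iron exporter gene Slc40a1 (-2.65, SE 0.084) and the oxysterol receptor gene Gpr183 (-2.62, SE 0.107). Fibroblast and stromal markers rose in 8 of 9 cases (camera adjusted p = 0.00045, and 0.089 with an estimated correlation), including Mmp2 (1.12, SE 0.0983) and Col6a1 (1.08, SE 0.0812; 0.24 and not passing with median scaling). With that scaling 2 of the 9 rose and 1 fell. Both measured lymphocyte markers fell. Neutrophil markers rose in 3 of 4 cases, and in none with median scaling (4 adjusted over the list alone; camera adjusted p = 0.055, and 0.22 with an estimated correlation; 0.018 to 0.22 over all alternatives). Camera passed for them without wild-type RIG-I ligand replicate 1 (0.037), knockout RIG-I ligand replicate 1 (0.047) or knockout CT DNA replicate 2 (0.048). Across all genes 2608 rose and 4532 fell, 976 and 750 of them by at least 1 log2 unit. The housekeeping gene Gapdh fell by 0.18 (SE 0.0605), but was at 0.09 with 75th percentile scaling. It did not pass there, with cyclic loess, or without wild-type untreated or RIG-I ligand replicate 2 (adjusted p = 0.055 and 0.060; 0.00016 to 0.88 over all alternatives).

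Wild-type cells given CT DNA, an agonist of cytosolic DNA sensing, also turned on interferon genes. Ifnb1 rose at least 656-fold and 12 of 13 interferon genes rose (camera adjusted p = 4.4e-12, and 0.0083 with an estimated correlation), Ifna11 at least 242-fold. Of 60 interferon-stimulated genes 58 rose and none fell (camera adjusted p = 2.0e-29, and 0.018 with an estimated correlation), such as Oasl1 (5.88, SE 0.0866) and Mx2 (5.77, SE 0.0937). Among 16 chemokines 13 rose and 1 fell (camera adjusted p = 8.0e-09, and 0.040 with an estimated correlation), such as Cxcl9 (8.99, SE 0.072) and Cxcl10 (6.57, SE 0.105). All 40 inflammatory cytokines and NF-kB targets rose (camera adjusted p = 1.9e-23, and 0.0018 with an estimated correlation). Cd69 (7.81, SE 0.127), Socs3, a brake on cytokine signalling (6.38, SE 0.0804), Tnf (3.68, SE 0.09), Il27 (at least 75.1-fold), Il1b (at least 8.42-fold) and Il6 (at least 3.06-fold) are examples.

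Heat shock genes rose in 7 of 12 cases and fell in 1 after CT DNA (camera adjusted p = 0.0066, and 0.033 with an estimated correlation), with the Hsp70 genes Hspa1a (7.41, SE 0.09) and Hspa1b (at least 26.6-fold) far ahead. Of 24 genes of the integrated stress response 9 rose and 7 fell, or 8 and 14 with median scaling (camera adjusted p = 0.115, and 0.21 with an estimated correlation). Among those that rose were Ppp1r15a, encoding a phosphatase subunit that reverses this response (5.53, SE 0.091), and Chac1, a glutathione-degrading enzyme (3.71, SE 0.133). Upp1, encoding uridine phosphorylase, rose by 7.37 (SE 0.11). Genes of cholesterol synthesis fell in 13 of 16 cases and rose in 1 (camera adjusted p = 0.0040, and 0.025 with an estimated correlation), among them Msmo1 (-2.52, SE 0.0797), Sqle (-1.69, SE 0.0776) and Stard4 (at least 7.08-fold lower). Cell cycle genes fell in 25 of 30 cases and rose in 4 (26 and 4 adjusted over the list alone; camera adjusted p = 1.5e-05, and 0.013 with an estimated correlation), such as Mcm4 (-1.66, SE 0.0767) and the thymidine kinase gene Tk1 (-1.53, SE 0.081). Sesn1 (-4.82, SE 0.131) and the myelin gene Mbp (-3.38, SE 0.118) also fell. Histone genes rose in 19 of 40 cases and fell in 11, or 7 and 22 with median scaling (camera adjusted p = 0.34, and 0.64 with an estimated correlation), with H2ac15 (-2.30, SE 0.104) among those down. Immediate early genes rose in 11 of 22 cases and fell in 4, or 8 and 11 with median scaling (camera adjusted p = 0.0086, and 0.16 with an estimated correlation), with Fos (-1.35, SE 0.136) down. Fibroblast and stromal markers rose in 8 of 9 cases (camera adjusted p = 7.1e-05, and 0.057 with an estimated correlation), with Dcn at 1.92 (SE 0.115). All 4 neutrophil markers rose (camera adjusted p = 0.0095, and 0.11 with an estimated correlation), with Lcn2 at 1.65 (SE 0.167), and both lymphocyte markers fell. Across all genes 3017 rose and 5016 fell, and the CT DNA arrays were on another chip than the untreated ones. Gapdh fell by 0.43 (SE 0.0605) but had a value of 0.11 with 75th percentile scaling.

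**Figure D2:**
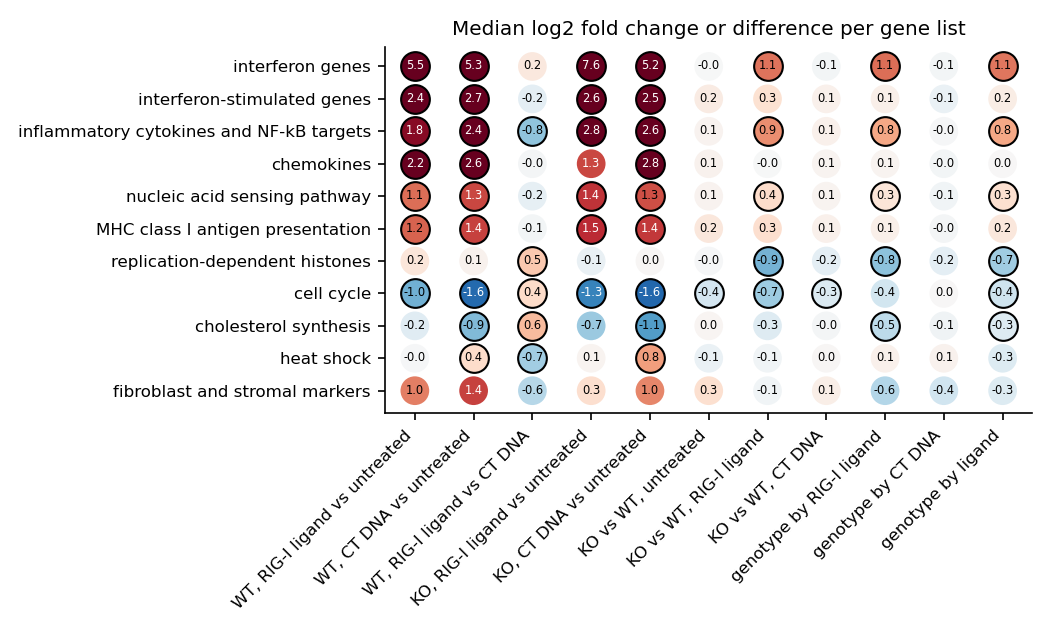
Median log2 fold change, or log2 difference for the interactions, of 11 gene lists (vertical axis) in the 11 comparisons (horizontal axis), n = 3 arrays per group; a black ring marks lists whose camera adjusted p was under 0.05 with both correlations. The interferon gene median was 5.52 and 5.30 in wild-type and 7.61 and 5.17 in knockout cells for the RIG-I ligand and CT DNA (4.93, 4.71, 6.98 and 4.54 with undetected genes at their floor); the histone median for the RIG-I ligand in knockout cells, -0.144, lies above the median of all genes and slightly below it with median or 75th percentile scaling.

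The RIG-I ligand and CT DNA were compared directly in wild-type cells. Histone genes were higher with the RIG-I ligand in 25 of 40 cases and lower in none (26 and 1 adjusted over the list alone; camera adjusted p = 3.2e-08, and 0.026 with an estimated correlation), such as H3c1 (2.09, SE 0.107), H3c4 (1.74, SE 0.0898) and H2ac6 (at least 3.31-fold). Also higher with the RIG-I ligand were the matrilin gene Matn4 (at least 10.3-fold), the immediate early genes Ier2 (at least 4.99-fold), Egr1 (2.34, SE 0.186) and Fos (1.07, SE 0.136), Fndc3a (at least 4.19-fold) and Hexim1, encoding an inhibitor of transcription elongation (2.48, SE 0.112). Of all 22 immediate early genes 7 were higher and 10 lower with the RIG-I ligand (7 and 11 adjusted over the list alone; camera adjusted p = 0.43, and 0.64 with an estimated correlation). Cholesterol synthesis was higher with the RIG-I ligand in 11 of 16 genes and lower in 1 (12 and 1 adjusted over the list alone; camera adjusted p = 0.00012, and 0.0086 with an estimated correlation), with Msmo1 at 1.51 (SE 0.0797) and Fdps at 0.77 (SE 0.0789). Cell cycle genes were higher in 17 of 30 cases and lower in 3 (21 and 3 adjusted over the list alone; camera adjusted p = 0.00034, and 0.025 with an estimated correlation).

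CT DNA gave the higher levels of inflammatory genes: 30 of 40 were lower with the RIG-I ligand and 2 higher (31 and 3 adjusted over the list alone; camera adjusted p = 3.3e-13, and 0.0075 with an estimated correlation). Socs3 (-2.32, SE 0.0804), Cd86, a costimulatory ligand (-2.36, SE 0.0843), Il27 (-2.21, SE 0.083) and Il1b (-2.33, SE 0.096) show the size. Heat shock genes were lower with the RIG-I ligand in 9 of 12 cases and higher in none (camera adjusted p = 4.3e-05, and 0.0075 with an estimated correlation), such as Hspa1a (-3.49, SE 0.09) and Hspa1b (-3.05, SE 0.173). Interferon-stimulated genes were lower in 27 of 60 cases and higher in 4 (camera adjusted p = 0.00047, and 0.38 with an estimated correlation), such as Zbp1, a sensor of Z-form nucleic acids (-2.24, SE 0.133), and Trim25 (-1.64, SE 0.0737). Single genes lower with the RIG-I ligand were Hopx (-3.82, SE 0.0668), Chac1 (-3.66, SE 0.133), Cxcl9 (-2.65, SE 0.072), Cxcl1 (-2.02, SE 0.0997) and Ifnb1 (-1.24, SE 0.0622). Yet 7 of 13 interferon genes were higher with the RIG-I ligand and 2 lower (camera adjusted p = 0.33, and 0.61 with an estimated correlation). Of them, 4 were higher with median, 75th percentile or cyclic loess scaling or without wild-type CT DNA replicate 1. Chemokines were higher in 4 of 16 cases and lower in 5, or 1 and 5 with median scaling (camera adjusted p = 0.13, and 0.52 with an estimated correlation; 0.0072 to 0.52 over all alternatives, passing with median and 75th percentile scaling). Integrated stress response genes were lower in 12 of 24 cases and higher in 8 (camera adjusted p = 0.032, and 0.10 with an estimated correlation). Fibroblast and stromal markers were lower with the RIG-I ligand in 6 of 9 cases (camera adjusted p = 0.0014, and 0.11 with an estimated correlation), and neutrophil markers in 4 of 4 (camera adjusted p = 0.017, and 0.135 with an estimated correlation). Of 16 p53 targets 8 were lower and 1 higher (camera adjusted p = 0.0023, and 0.040 with an estimated correlation). Macrophage identity genes were higher with the RIG-I ligand in 15 of 30 cases and lower in 3 (16 and 3 adjusted over the list alone; camera adjusted p = 0.0029, and 0.025 with an estimated correlation; 6.0e-07 to 0.17 over all alternatives). With median or 75th percentile scaling 7 of them were higher and camera did not pass. Across all genes 2667 were higher and 2340 lower with the RIG-I ligand, 197 and 400 of them by at least 1 log2 unit. Doses and chips differed between the ligands.

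Interferon and inflammatory genes also rose in knockout cells given either ligand. With the RIG-I ligand 12 of 13 interferon genes rose (camera adjusted p = 1.4e-12, and 0.0075 with an estimated correlation), Ifnb1 at least 618-fold and Ifna11 at least 525-fold. Of 60 interferon-stimulated genes 59 rose (camera adjusted p = 2.4e-29, and 0.018 with an estimated correlation), such as Oasl1 (5.13, SE 0.0866). Inflammatory genes rose in 38 of 40 cases (camera adjusted p = 2.9e-22, and 0.0018 with an estimated correlation), with Cd69 (8.01, SE 0.127), Socs3 (6.07, SE 0.0804), Tnf (3.00, SE 0.09) and Il27 (at least 156-fold). Of 16 chemokines 13 rose and 1 fell (camera adjusted p = 6.6e-08, and 0.052 with an estimated correlation), with Cxcl9 at 8.90 (SE 0.072) and Cxcl10 at 6.71 (SE 0.105). Cell cycle genes fell in 25 of 30 cases and rose in 1 (camera adjusted p = 2.7e-05, and 0.015 with an estimated correlation), with E2f1 at -2.11 (SE 0.0958). Cholesterol synthesis fell in 10 of 16 genes and rose in 1 (camera adjusted p = 0.031, and 0.074 with an estimated correlation), with Msmo1 (-2.19, SE 0.0797) and Sqle (-2.14, SE 0.0776). Histone genes fell in 19 of 40 cases and rose in 11 (camera adjusted p = 0.57, and 0.78 with an estimated correlation), with H2ac15 (-2.55, SE 0.104) and H2ac24 (-2.18, SE 0.0781) down. Sesn1 (-5.63, SE 0.131) and Srxn1, which repairs peroxiredoxins (-2.21, SE 0.0893), fell. Of 9 fibroblast and stromal markers 5 rose and 1 fell (camera adjusted p = 0.13, and 0.43 with an estimated correlation); none rose with median scaling. Both lymphocyte markers fell and both erythroid markers rose. In all, 2968 genes rose and 5136 fell, and of the 7140 genes past the threshold in wild-type cells 6140 passed in the same direction and 162 in the opposite one in knockout cells.

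CT DNA in knockout cells raised 12 of 13 interferon genes (camera adjusted p = 1.9e-11, and 0.0086 with an estimated correlation), Ifnb1 at least 555-fold, and 57 of 60 interferon-stimulated genes (58 adjusted over the list alone; camera adjusted p = 2.9e-28, and 0.020 with an estimated correlation), such as Oasl1 (5.68, SE 0.0866). All 40 inflammatory genes rose (camera adjusted p = 1.3e-22, and 0.0018 with an estimated correlation), including Cd69 (7.91, SE 0.127), Socs3 (6.74, SE 0.0804) and Il27 (at least 66.9-fold). Chemokines rose in 14 of 16 cases and fell in 1 (camera adjusted p = 1.1e-08, and 0.041 with an estimated correlation), Cxcl9 by 8.62 (SE 0.072) and Cxcl10 by 6.55 (SE 0.105). Heat shock genes rose in 9 of 12 cases and fell in 1 (camera adjusted p = 0.0011, and 0.018 with an estimated correlation), Hspa1a by 7.08 (SE 0.09). Cholesterol synthesis fell in 12 of 16 genes and rose in 1 (camera adjusted p = 0.0043, and 0.025 with an estimated correlation), with Msmo1 at -2.37 (SE 0.0797). Cell cycle genes fell in 24 of 30 cases and rose in 3 (camera adjusted p = 0.00014, and 0.022 with an estimated correlation), with Tk1 at -2.11 (SE 0.081). Pdia3, encoding a disulfide isomerase of the endoplasmic reticulum, was at background on all 3 arrays (at least 117-fold lower), and Maged1 was detected on 1 of them (-3.86, SE 0.79). The value of Pdia3 was the same on all 3 arrays (4.124, SD 0), and failure of a probe is not excluded for either gene. All 9 fibroblast and stromal markers rose (camera adjusted p = 0.00040, and 0.087 with an estimated correlation), as did all 4 neutrophil markers (camera adjusted p = 0.033, and 0.17 with an estimated correlation; 0.022 to 0.17 over all alternatives, 8 of which did not pass). Both lymphocyte markers fell and both erythroid markers rose. Across all genes 3167 rose and 5065 fell, and of the 8033 past the threshold in wild-type cells 6784 passed in the same direction and 123 in the opposite one.

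Untreated knockout cells were compared with untreated wild-type cells for the effect of the genotype at rest. Rnasel itself could not be read, since 0 probes carried its name. Erdr1 was undetected in knockout cells (at least 57.8-fold lower), and Ipo9, encoding an importin (-2.99, SE 0.16), Gdf3 (-2.52, SE 0.125), Rgl1, a neighbour of Rnasel on chromosome 1 (-2.16, SE 0.0813), and the macrophage elastase gene Mmp12 (-1.29, SE 0.108) were lower. Wdfy1 (1.93, SE 0.0676), the complement inhibitor gene Cd59a (1.39, SE 0.0756) and the chemokine gene Cxcl1 (1.27, SE 0.0997) were higher. The values of Rgl1 and Wdfy1 rest on 1 probe each, since their other detected probes stood at -0.0751 and 0.223. Of 16 chemokines 4 were higher and 3 lower (camera adjusted p = 0.19, and 0.59 with an estimated correlation), or 2 and 5 with median scaling. Only 2 were higher without wild-type untreated replicate 1 or 2 or knockout untreated replicate 2. Cell cycle genes were lower in 14 of 30 cases and higher in 1 (20 and 1 adjusted over the list alone; camera adjusted p = 3.4e-11, and 0.0018 with an estimated correlation), such as the mitotic genes Nusap1 (-0.87, SE 0.14), Plk1 (-0.74, SE 0.146) and Top2a (-0.55, SE 0.117). Interferon-stimulated genes were higher in 16 of 60 cases and lower in none (25 adjusted over the list alone; camera adjusted p = 1.4e-05, and 0.28 with an estimated correlation), with Zbp1 at 1.02 (SE 0.133) and Irf7, a master regulator of interferon, at 0.78 (SE 0.115). Fibroblast and stromal markers were higher in 5 of 9 cases (6 adjusted over the list alone; camera adjusted p = 3.3e-05, and 0.0501 with an estimated correlation, which loses the call; 3 of 9 with median scaling), with Col1a1 (1.07, SE 0.132), Col6a1 (0.88, SE 0.0812) and Sparc (0.80, SE 0.0913). Gapdh differed by -0.11 (SE 0.0605) and did not pass.

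Of all genes 617 were higher and 647 lower in untreated knockout cells, 11 and 17 of them by at least 1 log2 unit, and the genotypes were on different chips. The total of 1264 fell to 479 or 605 without wild-type untreated replicate 1 or 2 and to 816 or 718 without knockout untreated replicate 1 or 3. The cell cycle count of 14 became 5 or 9 without wild-type untreated replicate 1 or 2 and 9 or 8 without knockout untreated replicate 2 or 3. The count of 16 interferon-stimulated genes became 7 without wild-type untreated replicate 1 and 8 without knockout untreated replicate 2. With median scaling the total was 2665, of which 2569 were lower, 27 cell cycle genes were lower and 6 interferon-stimulated genes were higher.

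After the RIG-I ligand 5111 genes differed between the genotypes, in both directions. Interferon genes were higher in knockout cells in 10 of 13 cases and lower in 1 (camera adjusted p = 5.0e-08, and 0.021 with an estimated correlation), with Ifnb1 at 1.21 (SE 0.0622), Ifna9 at 2.49 (SE 0.092) and Ifna1 at 2.11 (SE 0.0815). Inflammatory genes were higher in 29 of 40 cases and lower in 2 (30 and 2 adjusted over the list alone; camera adjusted p = 3.7e-16, and 0.0046 with an estimated correlation): Il27 (3.32, SE 0.083), the inducible nitric oxide synthase gene Nos2 (2.44, SE 0.0942), Cd86 (2.00, SE 0.0843), Il1b (1.43, SE 0.096) and Il6 (1.31, SE 0.182). Higher in knockout cells were also the chemokine genes Cxcl9 (3.00, SE 0.072) and Ccl5 (1.17, SE 0.15), A630072M18Rik (3.75, SE 0.0868), Hopx (3.13, SE 0.0668), and Adamts4, a protease of the extracellular matrix (at least 9.91-fold). Cxcl10 (0.03, SE 0.105) and Tnf (0.19, SE 0.09) did not pass; Tnf passed with 6 alternatives, at 0.41 with 75th percentile scaling. Only 5 and 3 genes had a higher mean level than Cxcl10 in the wild-type and knockout RIG-I ligand groups, so its probe was near the top of the measured range. In the knockout RIG-I ligand group Ifnb1 had 36 genes above it, and Cxcl9 stood at 14.35 beside 14.7 for Cxcl10. Differences of Ifnb1 and Cxcl9 may thus be underestimated. Interferon-stimulated genes were higher in 33 of 60 cases and lower in 2 (34 and 2 adjusted over the list alone; camera adjusted p = 7.5e-07, and 0.23 with an estimated correlation), with Zbp1 up by 2.80 (SE 0.133) and Rnf213 lower (-1.92, SE 0.114). With median scaling 21 of the 60 were higher. Kept probes were called in opposite directions here for the interferon gene Ifna11. The same held for Dhx58, Oasl2, Parp14 and Parp9 among interferon-stimulated genes, so their values rest on 1 probe each.

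Histone genes were lower in knockout cells after the RIG-I ligand in 28 of 40 cases and higher in 1 (camera adjusted p = 1.5e-11, and 0.013 with an estimated correlation), with H3c6 (-3.20, SE 0.135), H3c4 (-2.48, SE 0.0898) and H3c1 (at least 4.22-fold lower). Hexim1 (-4.11, SE 0.112), Matn4 (at least 9.01-fold lower), the perforin gene Prf1 (-3.63, SE 0.178), and the immediate early genes Arc (at least 6.40-fold lower) and Ier2 (at least 4.36-fold lower) showed the same direction, as did the neutrophil-attracting chemokine gene Cxcl2 (-2.36, SE 0.102). Of all 22 immediate early genes 11 were lower and 5 higher (camera adjusted p = 0.15, and 0.42 with an estimated correlation; 0.023 to 0.78 over all alternatives, passing without the filter). Of 16 chemokines 6 were lower and 5 higher, or 3 and 6 with 75th percentile scaling (camera adjusted p = 0.68, and 0.85 with an estimated correlation). Cell cycle genes were lower in 25 of 30 cases and higher in 2 (27 and 2 adjusted over the list alone; camera adjusted p = 2.9e-07, and 0.0075 with an estimated correlation), such as Cdk1 (-1.04, SE 0.0949) and Tk1 (-0.88, SE 0.081). Macrophage identity genes were lower in 12 of 30 cases and higher in 3 (camera adjusted p = 0.069, and 0.13 with an estimated correlation; 0.00048 to 0.57 over all alternatives, some of which passed). Neutrophil markers were lower in 2 of 4 cases (camera adjusted p = 0.53, and 0.66 with an estimated correlation), such as S100a8 (-0.70, SE 0.109). Dendritic cell markers were lower in 3 of 6 cases and higher in 2 (camera adjusted p = 0.52, and 0.61 with an estimated correlation), with Clec9a at least 2.78-fold higher. Only 1 was lower without wild-type RIG-I ligand replicate 1 or 3 or knockout RIG-I ligand replicate 3, and none with cyclic loess. Both erythroid markers were higher, the globin gene Hbb-bs by 1.52 (SE 0.158). The housekeeping gene Gapdh differed by -0.32 (SE 0.0605) and passed, whereas Actb (0.06, SE 0.0641) did not. Of all genes 2129 were higher and 2982 lower, 362 and 315 of them by at least 1 log2 unit. This comparison crossed chips, whereas an additive difference between chips cancels in the test that follows.

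**Figure D3:**
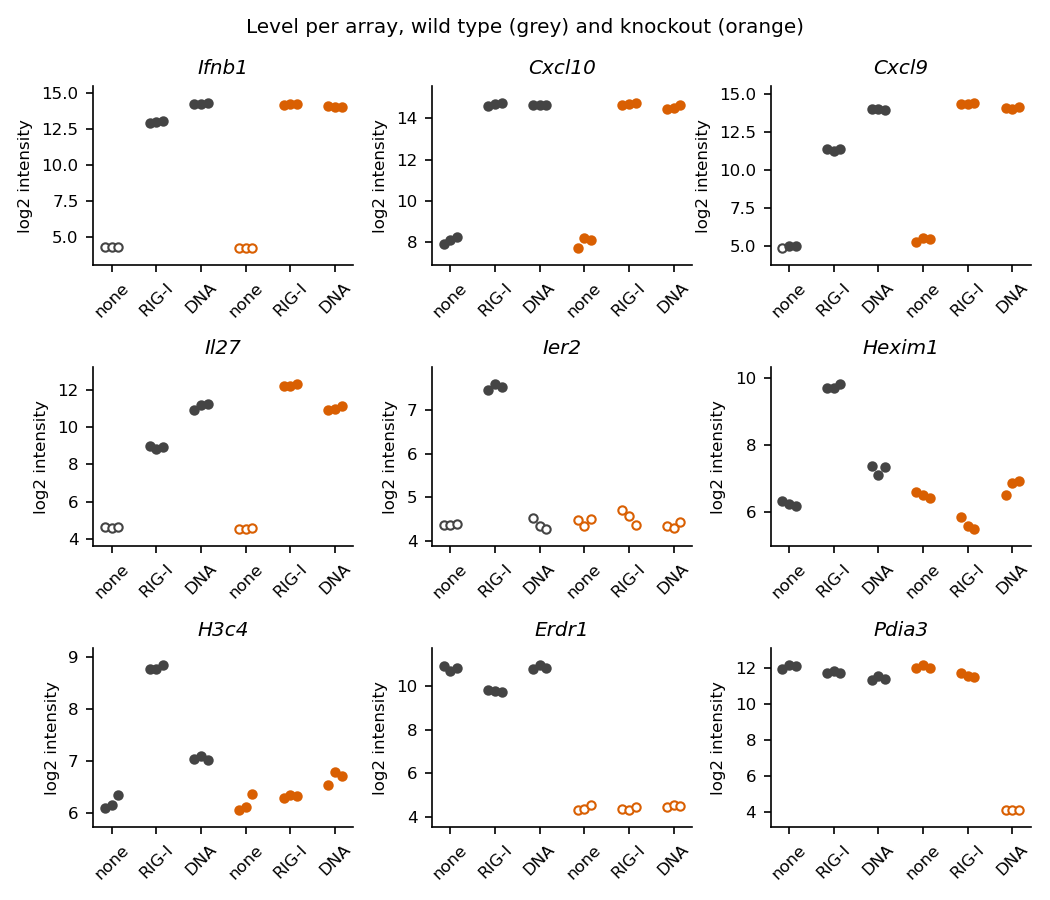
Log2 intensity (vertical axis) of 9 genes on each of the 18 arrays, wild-type in grey and knockout in orange, untreated (none), with the RIG-I ligand or with CT DNA (horizontal axis); open circles are arrays on which the probe was not detected. After the RIG-I ligand the knockout minus wild-type values were -4.11 for Hexim1, -2.48 for H3c4, 1.21 for Ifnb1 and 3.00 for Cxcl9.

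The genotype by RIG-I ligand interaction tested whether the response itself, measured within a chip for each genotype, differed. A chip difference that acts on the RIG-I ligand arrays alone would not cancel. It passed for 3098 genes, 1303 with higher and 1795 with lower values (knockout minus wild-type response), 342 and 266 of them by at least 1 log2 unit. Interferon genes had higher interaction values in 10 of 13 cases and a lower one in 1 (camera adjusted p = 2.1e-09, and 0.015 with an estimated correlation), inflammatory genes higher ones in 28 of 40 and lower in none (29 and 2 adjusted over the list alone; camera adjusted p = 2.1e-16, and 0.0046 with an estimated correlation). Among the interferon genes, kept probes of Ifna11 were called in opposite directions in this test, and probes of interferon alpha genes may cross-hybridize. Higher values were also found for A630072M18Rik (3.73, SE 0.123), Ppargc1b, a coactivator of mitochondrial genes (3.16, SE 0.172), Socs3 (2.01, SE 0.114) and the death receptor gene Fas (1.58, SE 0.11). Nucleic acid sensing genes had higher values in 9 of 24 cases and lower in 3 (11 and 3 adjusted over the list alone; 4 higher with median scaling; camera adjusted p = 0.0036, and 0.024 with an estimated correlation). Histone genes had lower values in 29 of 40 cases and higher in none (30 adjusted over the list alone; camera adjusted p = 1.0e-13, and 0.0086 with an estimated correlation), with H3c6 at -3.14 (SE 0.191) and H3c4 at -2.46 (SE 0.127). Hexim1 (-4.38, SE 0.158), the noncoding transcript Rab26os (-3.45, SE 0.19), Cxcl2 (-2.44, SE 0.145), Cxcl1 (-2.03, SE 0.141) and Sesn1 (-2.35, SE 0.185) had interaction values in the same direction. That of Cxcl1 holds its higher level in untreated knockout cells (1.27, SE 0.0997). Cholesterol synthesis genes had lower values in 9 of 16 cases and higher in none (10 adjusted over the list alone; camera adjusted p = 0.0036, and 0.025 with an estimated correlation), with Sqle at -1.20 (SE 0.11) and Msmo1 at -1.18 (SE 0.113). With median scaling the interaction passed for 2021 genes.

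Several lists passed the interaction test with the preset correlation alone. Interferon-stimulated genes had 11 of 60 members higher and 4 lower (camera adjusted p = 0.018, and 0.54 with an estimated correlation; 7.1e-05 to 0.54 over all alternatives). That call was lost without wild-type untreated replicate 2 or 3 (0.065 for each) or knockout untreated replicate 3 (0.082). Cell cycle genes had 2 higher and 15 lower (2 and 20 adjusted over the list alone; 8 lower with median scaling; camera adjusted p = 0.0095, and 0.087 with an estimated correlation). Antigen presentation by MHC class I had 4 of 22 genes higher (3 adjusted over the list alone; camera adjusted p = 0.0079, and 0.26 with an estimated correlation), and oxidative phosphorylation 13 of 64 lower (11 adjusted over the list alone; camera adjusted p = 0.0053, and 0.16 with an estimated correlation), 8 of them without wild-type untreated replicate 1. Ribosomal proteins had 5 of 52 lower (3 adjusted over the list alone; camera adjusted p = 0.047, and 0.35 with an estimated correlation). That count was 3 without wild-type untreated replicate 1, wild-type CT DNA replicate 3, or knockout untreated replicate 1 or 3, and its median lay above that of all genes with cyclic loess. Its camera call was lost without wild-type untreated replicate 1 or 3 (0.059 and 0.058), wild-type RIG-I ligand replicate 1 or 3 (0.051 and 0.062), knockout untreated replicate 2 or 3 (0.070 and 0.056) or knockout RIG-I ligand replicate 3 (0.12). Its range over all alternatives was 5.8e-05 to 0.55. Fibroblast and stromal markers, which rose in wild-type cells, had 7 of 9 members lower (camera adjusted p = 0.0041, and 0.15 with an estimated correlation). No call was made for chemokines (adjusted p = 0.66), immediate early genes (0.18; median below that of all genes, and above it with median, 75th percentile and cyclic loess scaling), the OAS and RNase L system (0.43), integrated stress response genes (0.95), heat shock (0.80), p53 targets (0.84), NRF2 targets (0.13), macrophage identity (0.16), neutrophil markers (0.29), dendritic cell markers (0.20) or chromosome 1 neighbours of Rnasel (0.42). Without the filter on detection, immediate early genes, NRF2 targets and macrophage identity passed (0.030, 0.029 and 0.0035; up to 0.55 for macrophage identity over all alternatives). Lists with 1 or 2 measured members were not tested as sets. Both erythroid markers passed upward, and 1 of 2 lymphocyte markers and the 1 mast cell marker passed downward. That mast cell marker, Kit, lay near background, and its value of -0.527 became -0.0121 with undetected groups at their floor. Neither of 2 sex-linked genes passed in limma, nor at an unadjusted p of 0.05 (0 genes).

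**Figure D4:**
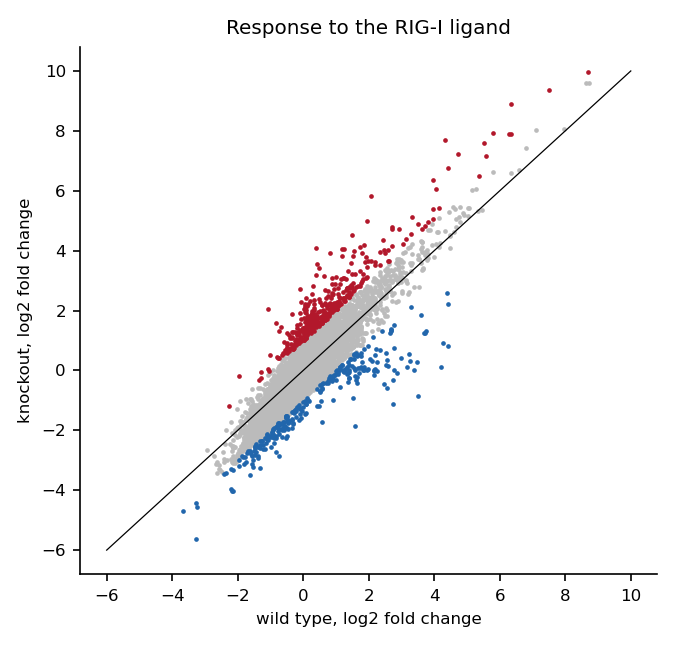
Log2 fold change with the RIG-I ligand in wild-type cells (horizontal axis) and in knockout cells (vertical axis), 1 point per gene, n = 3 arrays per group, with the line of equal response. Red and blue mark the 342 and 266 genes with a significant interaction of at least 1 log2 unit upward or downward in knockout cells.

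After CT DNA 1084 genes differed between the genotypes, and 2698 with median scaling (2619 higher and 79 lower). In limma 0 of 13 interferon genes passed (2 at an unadjusted p under 0.05; 0 adjusted over the list alone; 1 without wild-type CT DNA replicate 2 and 4 with median scaling; camera adjusted p = 0.84), with Ifnb1 at -0.19 (SE 0.0622; adjusted p = 0.068, and 0.012 to 0.81 over the alternatives, 5 of which passed) and Cxcl10 at -0.11 (SE 0.105). Only 6 and 13 genes had a higher mean level than Cxcl10 in the wild-type and knockout CT DNA groups, so this probe too was near the top of the measured range. Ifnb1 had 33 and 51 genes above it in the same groups, so its difference may be compressed as well. Interferon-stimulated genes were higher in knockout cells in 7 of 60 cases (29 with median scaling; camera adjusted p = 0.0029, and 0.45 with an estimated correlation). Cell cycle genes were lower in 10 of 30 cases and higher in none (18 adjusted over the list alone; 2 lower and 3 higher with median scaling; camera adjusted p = 1.9e-06, and 0.0086 with an estimated correlation), with Tk1 (-0.84, SE 0.081) and Aurka (-0.73, SE 0.115). Histone genes were lower in 15 of 40 cases and higher in 1 (18 and 3 adjusted over the list alone; 6 lower and 9 higher with median scaling; 9 lower without knockout CT DNA replicate 1; camera adjusted p = 0.00042, and 0.12 with an estimated correlation). Inflammatory genes were higher in 3 of 40 cases and lower in 3 (7 and 4 adjusted over the list alone; 20 higher with median scaling; 5 higher without knockout CT DNA replicate 3; camera adjusted p = 0.018, and 0.255 with an estimated correlation). That camera call was lost without wild-type CT DNA replicate 1 (0.094; 0.0029 to 0.255 over all alternatives). Macrophage identity genes were higher in 3 of 30 cases (8 adjusted over the list alone; 1 without wild-type CT DNA replicate 3 or knockout replicate 1 and 5 without knockout replicate 3; 12 with median scaling; camera adjusted p = 0.0054, and 0.032 with an estimated correlation). Dendritic cell markers were lower in 3 of 6 cases, and in none with median scaling (camera adjusted p = 0.0052, and 0.055 with an estimated correlation). Pdia3 (at least 76.3-fold), Erdr1 (at least 52.2-fold), Gdf3 (at least 4.72-fold), Maged1 (-3.89, SE 0.79), Rgl1 (-2.19, SE 0.0813), Ipo9 (-2.16, SE 0.16) and Tnf (-0.46, SE 0.09) were lower in knockout cells. Maged1 and Tnf did not pass when only these 2 groups were fitted (adjusted p = 0.11 and 0.072; up to 0.16 for Tnf over the alternatives, with median scaling). Wdfy1 (1.36, SE 0.0676; like Rgl1 from 1 of its probes), Cd59a (1.18, SE 0.0756) and the acute phase gene Saa3 (0.97, SE 0.167) were higher. Of all genes 425 were higher and 659 lower, 8 and 20 of them by at least 1 log2 unit. The total of 1084 was 174 when only these 2 groups were fitted, 502 without wild-type CT DNA replicate 3, and 437 or 696 without knockout CT DNA replicate 1 or 2. The 7 interferon-stimulated genes became 3 without wild-type CT DNA replicate 1 or 3 or knockout replicate 2, and 1 without knockout replicate 1.

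The genotype by CT DNA interaction passed for 783 genes upward and 873 downward, with 90 and 10 of at least 1 log2 unit. In limma 0 of 13 interferon genes passed (0 at an unadjusted p under 0.05; 0 adjusted over the list alone; 1 without wild-type CT DNA replicate 2; camera adjusted p = 0.89). Inflammatory genes had higher values in 6 of 40 cases and lower in 4 (8 and 5 adjusted over the list alone; camera adjusted p = 0.54). The 6 became 1 without wild-type untreated replicate 2, wild-type CT DNA replicate 3 or knockout untreated replicate 3. They became 2 without wild-type untreated replicate 1, wild-type CT DNA replicate 2 or knockout CT DNA replicate 1, and 3 without knockout untreated or CT DNA replicate 2. Among the lower ones was Tnf at -0.78 (SE 0.127; -0.31 and not passing with median scaling). Besides Pdia3 (at least 74.8-fold lower, as the knockout CT DNA group was at background) and Maged1 (-3.95, SE 1.12; detected on 1 array of that group), lower values were found for Cxcl1 (-1.19, SE 0.141) and the interferon-stimulated gene Ifit3 (-0.71, SE 0.16). The value of Cxcl1 holds its difference between untreated cells, where it was higher in knockout cells by 1.27 (SE 0.0997), on another chip. Of 60 interferon-stimulated genes 12 had lower and 3 higher values, or 0 and 21 with median scaling (13 and 4 adjusted over the list alone; 7 lower without knockout untreated replicate 2; camera adjusted p = 0.33, and 0.80 with an estimated correlation). Ifit3 did not pass with median scaling (-0.40) or the mean over its probes (-0.17). Maged1 did not pass without wild-type untreated replicate 1 or 2 (adjusted p = 0.051 and 0.056), wild-type CT DNA replicate 3 (0.053) or knockout CT DNA replicate 1 or 2 (0.073 and 0.065), and its range over all alternatives was 2.6e-13 to 0.073. Higher values were found for the protease gene Adam9 (1.42, SE 0.176), the tetraspanin gene Cd53 (1.41, SE 0.216) and the chaperone gene Hsp90aa1 (1.21, SE 0.145). Fibroblast and stromal markers had lower values in 4 of 9 cases (camera adjusted p = 0.013, and 0.21 with an estimated correlation; 0.0016 to 0.21 over all alternatives). That count was 2 without wild-type untreated replicate 1 or knockout CT DNA replicate 1, and the camera p was 0.058 without wild-type CT DNA replicate 2. The total of 1656 became 915 or 1022 without wild-type untreated replicate 1 or 2, 981 without wild-type CT DNA replicate 3, and 1017 without knockout CT DNA replicate 1. The 4 groups of this test lay on 4 chips, and with median scaling 4544 genes passed, 4512 of them upward.

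The genotype by ligand interaction asked whether the genotype difference after the RIG-I ligand departed from that after CT DNA. It was larger with the RIG-I ligand for interferon genes in 10 of 13 cases and smaller in 1 (11 and 1 adjusted over the list alone; camera adjusted p = 4.5e-09, and 0.016 with an estimated correlation), with Ifnb1 at 1.40 (SE 0.0879). Inflammatory genes had 26 of 40 members with higher values and 1 with a lower one (28 and 1 adjusted over the list alone; camera adjusted p = 3.7e-15, and 0.0056 with an estimated correlation), Cd86 at 1.99 (SE 0.119). Kept probes of the interferon gene Ifna11 were called in opposite directions in this test too. Ppargc1b (3.66, SE 0.172), A630072M18Rik (3.72, SE 0.123) and Tspan33 (3.37, SE 0.121) led the higher values among detected genes. Histone genes had 27 of 40 lower values and none higher (29 and 1 adjusted over the list alone; camera adjusted p = 4.4e-12, and 0.013 with an estimated correlation). Hexim1 (-3.61, SE 0.158), the serine racemase gene Srr (-2.60, SE 0.216) and Atf4, a regulator of the integrated stress response (-1.37, SE 0.13), were lower. Of 24 genes of that response 6 had lower and 5 higher values, or 14 and 2 with median scaling (6 and 6 adjusted over the list alone; camera adjusted p = 0.84, and 0.85 with an estimated correlation). Cell cycle genes had 13 of 30 lower values and 1 higher (16 and 1 adjusted over the list alone; 27 lower with median scaling; camera adjusted p = 0.0017, and 0.041 with an estimated correlation). Macrophage identity genes had 13 of 30 lower values and 2 higher (14 and 2 adjusted over the list alone; 22 lower with median scaling; camera adjusted p = 0.0040, and 0.027 with an estimated correlation; 2.2e-06 to 0.15 over all alternatives, not passing with median or 75th percentile scaling). Dendritic cell markers had 2 of 6 higher values (3 adjusted over the list alone; camera adjusted p = 0.0215, and 0.10 with an estimated correlation; 0.013 to 0.72 over all alternatives), and both erythroid markers had higher ones. In all, 1613 genes had higher and 1834 lower values, 350 and 309 of them by at least 1 log2 unit, and the 4 groups lay on 4 chips. With median scaling 5960 genes passed, 5557 of them downward.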

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

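The tests of chromosome 1 sequence, of second probes of Erdr1, Rgl1 and Wdfy1, of an additive difference between BeadChips, and of a set of weak probes were chosen after the results they address were seen. The results in this part are differences between groups: an effect of treatment differed between genotypes, or an effect of genotype between ligands, in an interaction test.

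The genotype by RIG-I ligand interaction passed for 3098 genes, that with CT DNA for 1656 and that between ligands for 3447. With the RIG-I ligand the median log2 difference was 1.11 for interferon genes (1.04 with undetected genes at their floor), 0.779 for inflammatory genes, 0.256 for nucleic acid sensing genes, -0.825 for histone genes (-0.722 at the floor) and -0.516 for cholesterol synthesis (-0.428 at the floor). Single genes were A630072M18Rik (3.73), Ppargc1b (3.16), Socs3 (2.01), Fas (1.58), Hexim1 (-4.38), Rab26os (-3.45), H3c6 (-3.14), H3c4 (-2.46), Cxcl2 (-2.44), Cxcl1 (-2.03), Sesn1 (-2.35), Sqle (-1.20) and Msmo1 (-1.18). With CT DNA they were Pdia3 (a fitted -7.25 with 1 group at background, at least 74.8-fold), Maged1 (-3.95), Cxcl1 (-1.19), Tnf (-0.78), Ifit3 (-0.71), Adam9 (1.42), Cd53 (1.41) and Hsp90aa1 (1.21). Between ligands the list medians were 1.07 for interferon genes, 0.779 for inflammatory genes, -0.709 for histone genes (-0.683 at the floor), -0.413 for cell cycle genes (-0.333) and -0.272 for macrophage identity (-0.17). Genes there were A630072M18Rik (3.72), Ppargc1b (3.66), Tspan33 (3.37), Cd86 (1.99), Ifnb1 (1.40), Hexim1 (-3.61), Srr (-2.60) and Atf4 (-1.37).

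Hexim1, H3c4 and other transcripts had lower interaction values, and Ifnb1, Il27 and Cxcl9 were higher, in knockout cells given the RIG-I ligand. An additive difference between the 2 chips cancels in this test, and untreated arrays of the same chips differed by at least 1 log2 unit in 28 genes against 608 in the interaction. In all, 283 genes responded by at least 1 log2 unit in wild-type cells and also differed between genotypes by at least 1 log2 unit. Of these 60.1% moved further in their wild-type direction: 114 rose more and 104 less, whereas 56 fell more and 9 less. The 104 genes that rose less argue against a uniformly stronger knockout response. Other between-array normalizations left at least 543 of such genes, though smaller folds without background correction or with an offset of 50 left 191 and 334. Loss of RNase L and a difference between chips that acts on the RIG-I ligand arrays alone may each explain the pattern, and neither was tested.

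Pdia3 was at background on all 3 knockout CT DNA arrays (mean log2 level 4.124), whereas Maged1 was detected on 1 of them and not on the others (mean 5.741, SD 2.78). The value of Pdia3 was the same on all 3 arrays (SD 0), below the mean of 4.488 of the undetected Erdr1 there. Identical values may follow from failure of a single probe. Such failure stays open, since 0 other detected probes of either gene exist, and the folds of both genes may not measure transcript levels. Beside them, 90 genes such as Adam9 and Cd53 had interaction values of at least 1. Their median knockout minus wild-type differences were -0.645 untreated, -0.399 after the RIG-I ligand and 0.512 after CT DNA, so lower signal of a set of probes on the chip of the first 2 groups cannot be told apart from a genotype effect. Each group lies on 1 chip, which keeps both open, and no biological explanation was tested.

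Erdr1, Gdf3, Ipo9 and Rgl1 were lower and Wdfy1 was higher in knockout cells in all 3 conditions by at least 1 log2 unit. Of these 5 genes 2 (40%), Ipo9 and Rgl1, lie within 20 Mb of Rnasel on chromosome 1, against 1.39% of 8906 placed genes (exact hypergeometric p = 0.00187). The test was chosen after these genes were seen, so that p is descriptive. The list of chromosome 1 neighbours fixed in advance, with 17 measured genes and without Ipo9, was not called between genotypes. Its camera adjusted p was 0.23 untreated, 0.74 after the RIG-I ligand and 0.62 after CT DNA. Sequence carried over from another strain around the targeted gene stays a candidate explanation. For Erdr1 a single sequence difference under the probe is argued against by its other probe, at -2.86. The other probes of Rgl1 (-0.0751) and Wdfy1 (0.223) hardly differed, so a sequence difference under a single probe stays a candidate explanation for these. An effect of RNase L on these genes was not tested.

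For the 8 comparisons of 2 groups only 10 splits of the 6 arrays exist, too few for a share under 0.05. The real counts were 7140, 8033, 8104 and 8232 for the RIG-I ligand and CT DNA in wild-type, then knockout cells, with 0 as the highest of the other splits in limma. They were 1264, 5111 and 1084 between genotypes untreated, after the RIG-I ligand and after CT DNA, against 1 at most, and 5007 between ligands in wild-type cells against 2. In each of these, 1 split, the real one, gave a count as large. For the genotype by RIG-I ligand interaction 7 of 100 splits gave a count as large (highest other 4742, real 3098), so chance is not excluded by that share. All 6 others kept the genotypes apart in the RIG-I ligand arrays and mixed or exchanged them among the untreated ones, which points to the structure of those arrays; with RIG-I ligand arrays mixed, the highest count was 51. For CT DNA 1 of 100 splits did (highest other 757, real 1656), a share under 0.05. That highest other count came from a split that kept the genotypes of the untreated arrays apart and mixed the CT DNA ones. The splits drawn for CT DNA did not include an exchange of the genotypes in 1 condition alone, which gave 4742 genes for the RIG-I ligand. The 2 shares are thus not comparable, and the share for CT DNA does not exclude chance. Between ligands 4 of 100 did (highest other 3534, real 3447), also under 0.05. There the 3 others also kept the genotypes of the RIG-I ligand arrays apart. Splits that kept these apart and mixed the CT DNA arrays gave 2814 to 3534 genes, and those that mixed the RIG-I ligand arrays at most 15. That count thus follows the genotype difference after the RIG-I ligand, and the share cannot test a difference between ligands.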

How the results depend on the processing

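All alternatives were chosen before the data were examined. They left 345 of 374 gene counts within 1.5 times their value, 6756 of 6790 results for named genes and 2927 of 3036 camera results on the same side of the threshold and in the same direction, and 2900 of 3036 list counts within 1.5 times. Named gene results became weaker in 17 cases, stronger in 11 and reversed in 6; for camera the numbers were 70, 18 and 21. Excluding the fold threshold, counts ranged from 5420 to 9728 for the RIG-I ligand and 5921 to 11241 for CT DNA in wild-type cells, 5964 to 11283 and 6174 to 11490 in knockout cells, 479 to 2665, 3960 to 6995 and 174 to 2698 between genotypes untreated, with the RIG-I ligand and with CT DNA, 2021 to 4086, 915 to 4544 and 2738 to 5960 for the RIG-I ligand, CT DNA and ligand interactions, and 3980 to 6859 between ligands. Where no cause follows from the alternative itself, the cause was not tested. A fold threshold of 1 log2 unit, which keeps fewer genes by construction, left 1726, 2585, 2737 and 2779 for the treatments, 28, 677 and 28 between genotypes, 608, 100 and 659 for the interactions and 597 between ligands.

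With median scaling the counts were 2665 (96 higher, 2569 lower) between genotypes untreated, 2698 (2619 and 79) after CT DNA, and 2021 (991 and 1030), 4544 (4512 and 32) and 5960 (403 and 5557) for the RIG-I ligand, CT DNA and ligand interactions. These moved with the median of all genes, at -0.197, 0.205, -0.0315, 0.393 and -0.441. Cell cycle genes lower in knockout cells became 27 untreated, 2 after CT DNA and 27 in the ligand interaction. Macrophage identity genes became 12 higher after CT DNA and 22 lower in the ligand interaction (camera 0.107). Nucleic acid sensing genes with higher values became 4 in the RIG-I ligand interaction. Between ligands in wild-type cells macrophage identity had 7 higher genes and lost its camera call (0.169), also with 75th percentile scaling (7 and 0.151). Cxcl10 after the RIG-I ligand was -0.0112, and camera for interferon genes after CT DNA 0.858, both reversed. With 75th percentile scaling Gapdh reversed to 0.0854 with the RIG-I ligand and 0.11 with CT DNA in wild-type cells, camera for interferon genes after CT DNA reversed (0.985), macrophage identity gave 7 genes after CT DNA and lost its call in the ligand interaction (0.145). Cyclic loess also gave 7.

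Without background correction and with the deposited values, cell cycle genes numbered 22 between untreated genotypes and macrophage identity genes 8 after CT DNA, and camera for interferon genes in the CT DNA interaction reversed (0.939 and 0.94). Detection on all 18 arrays, which tests fewer genes, left 17 cell cycle genes lower with the RIG-I ligand and 8 and 7 cholesterol genes lower with CT DNA in wild-type and knockout cells, and gave 6 macrophage genes after CT DNA. In the RIG-I ligand interaction it reversed camera for chemokines (0.752), integrated stress response (0.752) and dendritic cell markers (0.574), and no filter reversed it for chromosome 1 neighbours (0.998). For dendritic cell markers between genotypes after the RIG-I ligand camera reversed with both filters (0.252 and 0.95). Detection on all 18 arrays also reversed camera for chemokines there (0.775) and for the integrated stress response in the ligand interaction (0.989). The mean over probes reversed Cxcl10 after the RIG-I ligand (-0.13) and CT DNA (0.0873). Array weights gave 1950 between untreated genotypes, and fitting only the groups compared, with fewer arrays, 174 after CT DNA. Adjusted over the list alone, 18 cell cycle and 8 macrophage genes passed after CT DNA. The replicate block gave 5 macrophage genes after CT DNA, but replicate numbers were not taken to pair arrays. Deviations of arrays with the same number in different groups correlated across genes with a median r of 0.000821 (-0.109 to 0.141), and 5 of 45 such pairs were over 0.1. The highest value for different numbers was 0.0971, and 12 of 18 arrays correlated best with their own number, a hint of weak pairing.

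Leaving out 1 array at a time gave 479 to 1351 genes between untreated genotypes, 437 to 1113 after CT DNA and 915 to 1731 in the CT DNA interaction. Cell cycle genes ranged from 5 to 17 between untreated genotypes and macrophage identity genes from 1 to 5 after CT DNA. Cxcl10 ranged from -0.00817 to 0.0545 after the RIG-I ligand. Camera ranged from 0.247 to 0.95 and 0.422 to 0.991 for interferon genes after CT DNA and in its interaction, and from 0.839 to 0.988 for the integrated stress response in the RIG-I ligand interaction. These fits hold fewer arrays. A fit with BeadChip as a block was not run because each group lies on 1 chip, and leaving out a chip would remove whole groups. Signal over background limits genes near the floor, which are given as bounds where a group was undetected.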

Other observations

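The ligand comparison between genotypes was tested only after the wild-type result was seen; the test of short genes was written before its result. In knockout cells the RIG-I ligand and CT DNA groups differed in 4131 genes (2000 higher and 2131 lower with the RIG-I ligand), and in 254 by at least 1 log2 unit, against 597 in wild-type cells. Hopx differed by -3.82 in wild-type and -0.727 in knockout cells, Cd86 by -2.36 and -0.374, and Cxcl9 by -2.65 and 0.283. In the knockout RIG-I ligand and CT DNA groups Cxcl9 stood at 14.35 and 14.06, beside 14.7 and 14.55 for Cxcl10. The knockout difference of Cxcl9 may thus be compressed near the top of the measured range. Il27 differed by -2.21 and 1.22, Hspa1a by -3.49 and -2.9, Chac1 by -3.66 and -2.37, and Egr1 by 2.34 and 1.68. Over the 597 genes the median ratio of the knockout to the wild-type difference was 0.175, and 560 differed less in knockout cells. A ratio below 1 is partly fixed by choosing genes on the wild-type values. A candidate explanation is that the contrast between the ligands depends on the genotype, but the 4 groups lie on 4 chips.

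A hypothesis that transcripts higher in wild-type than in knockout cells after the RIG-I ligand come from short genes was tested, as histone genes and Ier2 are short. The sets tested held only part of the 2982 lower and 2129 higher genes in knockout cells. Without histones the median span of a set of 178 genes higher in wild-type cells was 18 kb. This lay inside the range of 17.4 to 26.4 kb of sets matched on level, the outcome set beforehand as going against short genes. As it was just above the lower end of that range, short length is not excluded. With histones it was 15 kb, below the matched range (195 genes, 17.6 to 26 kb). The set of 298 genes higher in knockout cells had a median of 25.9 kb, above its matched range (17.9 to 25.2 kb).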
